A study of Mus musculus with 16 samples.

How the data were processed

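RNA was measured on 16 Affymetrix-type arrays of myeloid progenitors from the bone marrow of C57BL/6 mice. Per the labels, mice drank either control water or water with a mixture of vancomycin, neomycin, ampicillin and metronidazole, each at 1 g/L, for 3 weeks, both sweetened with 2% sucrose. Cells negative for the lineage markers and CD105 and positive for Kit were sorted by CD16/32, CD115 and Ly6C into common myeloid progenitors (CMPs, intermediate CD16/32), granulocyte-monocyte progenitors (GMPs, high CD16/32) and committed monocyte progenitors (cMoPs, positive for CD115 and Ly6C). The lineage antibodies included one against Sca-1. RNA was isolated with a Qiagen micro kit, 2.6 ng of it was amplified with a NuGen whole-transcriptome kit, and the cDNA was labelled with biotin. A gate for a further progenitor is described in the sort protocol, and no sample of it is among those used here.

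The deposited table holds 1 log2 signal per probe set and array, made by the authors with Partek and Transcriptome Analysis Console per the submitters' processing notes. Their versions, the summarisation and the normalization between arrays are not given in the sources used here. The values have 2 decimals, none is missing, and the quartiles of the 16 arrays are close to each other (lower 2.89 to 2.99, median 4.04 to 4.17, upper 6.24 to 6.41), so they were used as deposited. The table has no detection calls, so a group mean below the lower quartiles is not shown to be above background. Where water was compared this holds, among others, for Fabp4 in control cMoPs (2.63), BC051142 in control GMPs (2.62), Hormad2 in GMPs after antibiotics (2.71) and Zfp811 in CMPs after antibiotics (2.19). It also holds for Pkhd1l1 in GMPs and cMoPs of both waters (2.62 to 2.8) and for some of these genes in the progenitors where they were not called. Where progenitors were compared it holds, among others, for Ctla2a in cMoPs after antibiotics (2.84), so the size of such a fall is uncertain. For arrays there is no count per sample, and the number of arrays limits the precision.

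Of the 41345 probe sets of the table, 23521 carried 1 gene symbol and were used. The 1814 with several symbols and the 16010 with none were not used here, except in the alternative that tests every probe set. Symbols were checked through the gene identifiers, which matched for 23328 probe sets and not for 193, and 0 symbols changed. For the 1082 genes with more than 1 probe set, the one with the highest mean over all arrays was taken, which left 22180 genes. No filter on dim genes was applied.

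Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups of progenitor and water and 10 residual degrees of freedom. Moderated variances came from eBayes (prior degrees of freedom 5.28, prior SD 0.199). The stated design of the study is a 2-way analysis of variance with a Benjamini-Hochberg false discovery rate under 0.2, so this rate was used for the effects of antibiotics, both within each progenitor and as the equal-weight mean of the 3 within-progenitor differences. Whether the effect differed between progenitors was tested with an F test on the interaction at the same rate. Differences between progenitors, averaged over both waters, were called at a rate under 0.05. Every adjusted p is a Benjamini-Hochberg value of limma over the genes tested unless said otherwise, every test is two-sided, and errors of differences are standard errors. Differences are antibiotic minus control, or the progenitor named first minus the other, in log2.

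A total of 28 gene lists with 758 entries were written down, 683 of which were measured. Of these lists, 26 were tested: type I interferon response, interferon-gamma response, Toll-like receptor and NF-kB signalling, immediate early genes, the unfolded protein and integrated stress response, glucocorticoid response, circadian clock, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, S phase, G2 and M phase, cytokine and growth factor receptors, and markers of 12 cell types or stages (stem and multipotent progenitors, megakaryocytes, erythroid cells, primary granules and early neutrophils, late granules and mature neutrophils, monocytes, macrophages, dendritic cells with MHC class II, eosinophils with basophils and mast cells, B lineage, T and NK cells, stromal and endothelial cells). The genes of the sort gate and the sex-linked genes served as checks of the labels. Lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and a false discovery rate under 0.05 over the 26 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way and compares them with no other genes, were run beside it. For each list the members called over all genes were counted, and also the members called when adjusted over the list alone. The matching of list entries to symbols was corrected after first results had been seen, because 3 entries had been matched to other genes. The correction added glycolysis to the lists called in CMPs.

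Genes named in the text follow a rule: per comparison, the 10 largest rises and the 10 largest falls among the genes called (all of them where fewer were called), the 10 of smallest p for the interaction, the 4 members of smallest p of each list described, and all genes of the sort gate. Genes with the names of predicted genes (Gm, Rik, LOC), olfactory receptors or microRNAs were counted and passed over for the next. They made up 15 of the genes called over the 3 progenitors, 1 in CMPs, 3 in GMPs and 4 in cMoPs, and Mir186, Mir23a and Olfr695 are named besides, chosen after their values were seen. The groups, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. An exact permutation test of each list's mean, over the 2000 assignments of water within the progenitors, was added after the data had been seen, as were the values of the type I interferon list under the alternatives.

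The correlation of antibiotic effects between progenitors was computed across genes and set against 100 regroupings of the water labels within each progenitor. Principal components were computed in R from the 9567 genes with a mean log2 signal above 5. The alternatives were quantile normalization, median centring, a filter that kept genes brighter than the median gene, all probe sets, the mean of the probe sets of a gene, an unmoderated 2-way analysis, eBayes with trend and robust variances, array weights, the replicate number as a fixed or random block, an additive model, other thresholds, fits of only the groups compared, contrasts of only the control groups, and leaving out each array in turn. Where that left 1 array in a group, it was assumed to vary like those of the other groups. The labels do not say whether the same replicate number in different groups means shared animals. The samples were treated as unpaired. The permutation test and the regroupings of water shuffle the labels in each progenitor separately. They too assume that the arrays of different progenitors share no animals.

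The calls were tested on simulated data with the same design and 22180 genes. True differences of 1 log2 unit were recovered for 94% of genes over the 3 progenitors, 88.1% in CMPs, 71.6% in GMPs, 73.1% in cMoPs and 50.7% for the interaction. At 0.5 log2 units the recovery was 71.6% over the 3 progenitors, 22.4% in CMPs, 25.4% in GMPs and in cMoPs, and 4.5% for the interaction. Of the simulated calls over the 3 progenitors, 43 of 220 were false. A list lowered by 0.3 log2 units was called by each of the 4 list tests. The simulated genes varied independently of each other. This does not show how the list tests behave for correlated genes, where they differ. Tables were prepared with Python 3.11.15 and pandas 2.3.3, the random block used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9.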

Results

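Expression was measured on 16 arrays of bone-marrow myeloid progenitors, from mice given antibiotic water and from mice given control water. CMPs had 3 antibiotic and 3 control arrays, and GMPs and cMoPs each had 3 antibiotic and 2 control arrays. The labels do not say whether each array came from a separate mouse or from a pool, so the p-values measure the spread between these samples, and the number of arrays limits the precision. The median log2 signal of the arrays lay between 4.04 and 4.17. Arrays of the same group correlated across genes at r = 0.985 to 0.991 over 14 pairs, and arrays of different groups at 0.961 to 0.991 over 106 pairs. Genes are not independent replicates. On the first principal component, with 56.4% of the variance, and the second, with 14.5%, the arrays lay apart by progenitor. On the third, with 4.3%, the antibiotic arrays lay between -11.5 and 1.3 and the control arrays between 1 and 15. On the fourth, with 3.1%, cMoP control 1 stood apart at 19.2. Xist, the X-inactivation RNA, had group means of 11.2 to 11.8, and the Y-linked genes Kdm5d, Eif2s3y and Uty had group means no higher than 2.77 in any group.

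**Figure D1:**
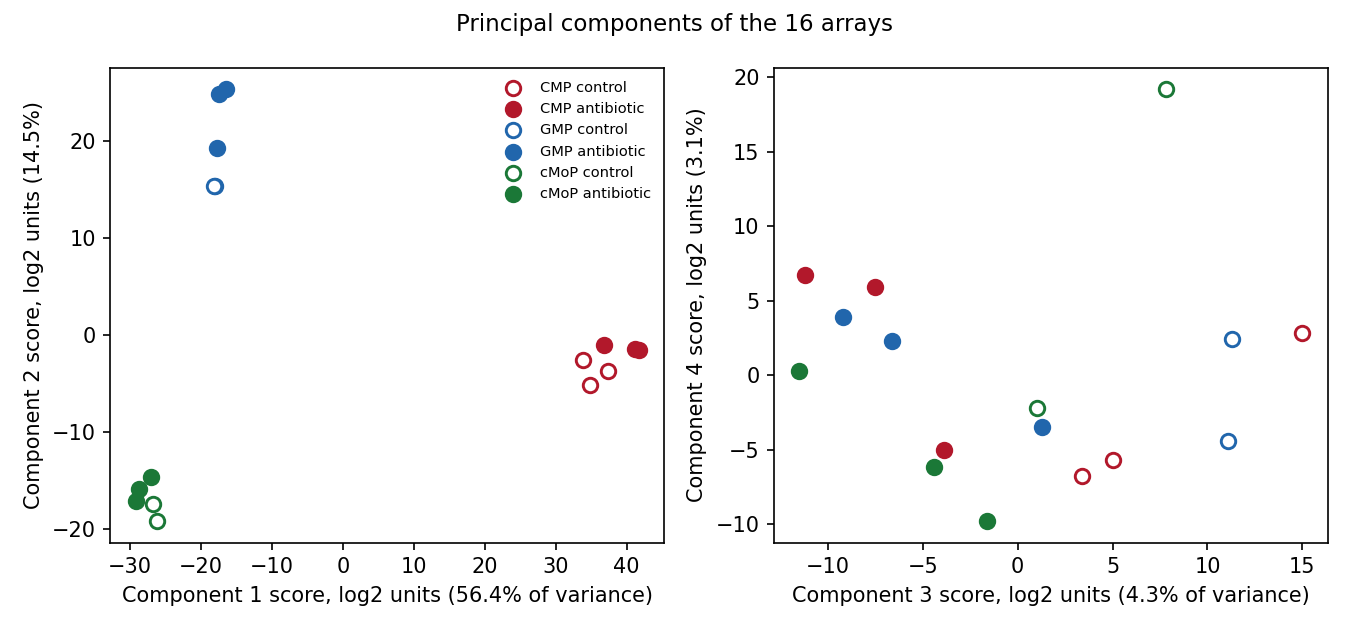
Scores of the 16 arrays on principal components 1 and 2 and on components 3 and 4, with open symbols for control and filled symbols for antibiotic water. The progenitors lie apart on the first components, and on component 3 the antibiotic arrays lie between -11.5 and 1.3 and the controls between 1 and 15.

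The effect of antibiotics averaged over CMPs, GMPs and cMoPs answers the question of which genes differ between progenitors of treated and control mice. Among the genes that rose was Fabp4, a fatty-acid-binding protein (probe set 17404091; log2 difference 1.38 ± 0.24 SE, adjusted p = 0.0342). Fbp1, the fructose-bisphosphatase of gluconeogenesis (probe set 17293557), rose 2.52-fold (1.33 ± 0.2, adjusted p = 0.0149). The largest falls were in Ppic, a peptidyl-prolyl isomerase (-1.13 ± 0.12, adjusted p = 0.0016), and Gdf3, a ligand of the TGF-beta family (-0.97 ± 0.13, adjusted p = 0.00846). In all, 114 of 22180 genes were called, 60 higher and 54 lower after antibiotics. Of them, 109 had the same sign in the 3 progenitors and 6 differed at least 2-fold. A call on the mean of the 3 differences itself favours genes with the same sign throughout. The 109 therefore do not show that the progenitors agreed. Fabp4 differed by 1.96 ± 0.38 in CMPs, 1.19 ± 0.43 in GMPs and 1 ± 0.43 in cMoPs, with an SD of 0.95 between the CMP control arrays. Its mean in control cMoPs was 2.63, below the lower quartile of every array, a level not shown to be above background. Fbp1 differed by 1.07 ± 0.32, 1.31 ± 0.36 and 1.63 ± 0.36 in the same order.

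Chil3, a chitinase-like protein of myeloid cells, rose by 0.89 ± 0.13 and the C-type lectin genes Clec4b2 and Clec4a2 by 1 ± 0.14 and 0.83 ± 0.1. In CMPs alone Clec4b2 differed by 0.06 ± 0.23 and Clec4a2 by -0.55 ± 0.16. These lectin genes are paralogs, and whether their probes tell them apart was not tested. Cpa3, a mast cell protease, rose by 0.81 ± 0.12, Zbtb16, the transcription factor PLZF, by 0.83 ± 0.12, and Car1, a carbonic anhydrase of red cell precursors, by 0.86 ± 0.11. The adjusted p of these 6 genes lay between 0.0036 and 0.0143. Of the small nucleolar RNAs, which guide the modification or cleavage of other RNAs, Snord13 rose by 0.94 ± 0.09 (adjusted p = 0.000892) and Snord72 by 1.1 ± 0.23 (adjusted p = 0.123). Snord118 fell by 0.91 ± 0.19 (adjusted p = 0.119). The other 69 small nucleolar RNA genes had a median difference of 0.089. Grb10, an adaptor of the insulin receptor, fell by 0.72 ± 0.14 (adjusted p = 0.0688), Smco4 by 0.74 ± 0.13 (adjusted p = 0.035) and Car13, another carbonic anhydrase, by 0.83 ± 0.18 (adjusted p = 0.123). The microRNA gene Mir186 rose by 1.04 ± 0.23 (adjusted p = 0.145) and Mir23a fell by 0.96 ± 0.2 (adjusted p = 0.119). Their differences were uneven: in CMPs, GMPs and cMoPs they were 2.02, -0.17 and 1.27 for Mir186 and -0.34, -2.15 and -0.4 for Mir23a. Of the 114 genes, 23 passed a false discovery rate of 0.05. Among all genes, 2115 genes had an unadjusted p under 0.05, where 1109 would by chance. The count depended on single arrays: it was 41 without CMP antibiotic 1 or without cMoP antibiotic 1, 45 without GMP antibiotic 2, 51 without CMP control 1 and 56 without cMoP antibiotic 2. It was 57 without cMoP control 1 or without GMP control 2, 66 without GMP antibiotic 1, 67 without CMP antibiotic 2 and 269 without cMoP control 2. The count was 59 with all probe sets tested, 353 with only genes brighter than the median gene, and 350 with trend and robust variances.

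**Figure D2:**
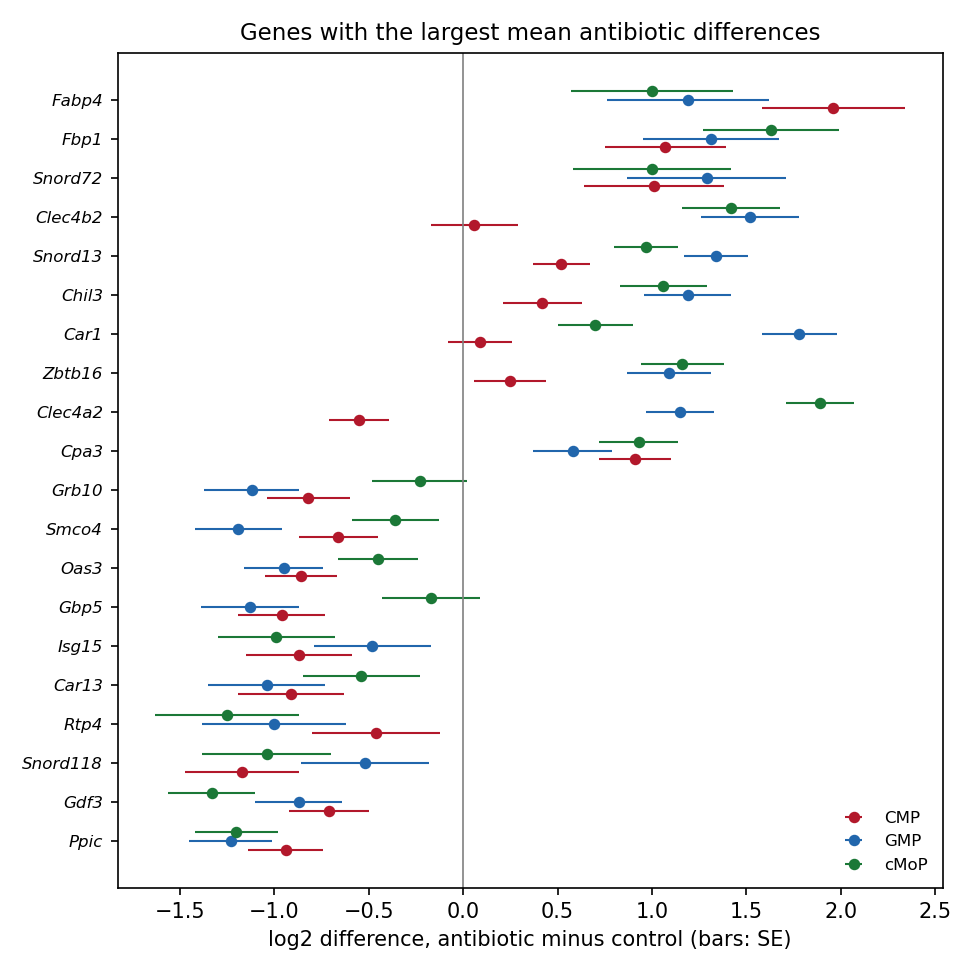
Log2 difference, antibiotic minus control, of the 10 genes with the largest rise and the 10 with the largest fall called over the 3 progenitors, with microRNAs, olfactory receptors and predicted genes passed over, as points with standard errors for CMPs, GMPs and cMoPs. Fabp4 lies at 1.96 in CMPs, 1.19 in GMPs and 1 in cMoPs, and Clec4b2 at 0.06, 1.52 and 1.42.

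Genes induced by type I interferon were lower as a list after antibiotics over the 3 progenitors. With an estimated correlation the list passed for their mean (adjusted p = 0.048) but not within CMPs (adjusted p = 0.0717), GMPs (adjusted p = 0.467) or cMoPs (adjusted p = 0.661). Of the 36 measured members of the list, 33 had a negative difference over the progenitors. Over all genes 7 were called lower, and 18 were called lower when adjusted over the list alone. Among them were Oas3, which makes the activator of RNase L (-0.75 ± 0.12, adjusted p = 0.017), and Ifitm3, an inhibitor of virus entry (-0.47 ± 0.09, adjusted p = 0.0576). Others were Isg15, a ubiquitin-like protein (-0.78 ± 0.17, adjusted p = 0.148), and Rtp4 (-0.9 ± 0.21, adjusted p = 0.18). Parp14 and Oasl2 were also called, at -0.41 ± 0.08 (adjusted p = 0.105) and -0.64 ± 0.14 (adjusted p = 0.124). The mean log2 signal of the list was 6.00 ± 0.133 (SD, n = 3) after antibiotics and 6.33 ± 0.04 (n = 3) in controls in CMPs. The corresponding values were 5.65 ± 0.139 (n = 3) and 5.90 ± 0.083 (n = 2) in GMPs, and 5.49 ± 0.072 (n = 3) and 5.76 ± 0.127 (n = 2) in cMoPs. Within each progenitor every antibiotic array lay below every control array. The 39 brighter markers of macrophages, dendritic cells, B cells, T and NK cells had a mean difference of 0.063 ± 0.039. The mean difference over the progenitors was -0.29 and the median -0.24 (camera adjusted p = 1.13e-12; fry adjusted p = 0.00279). In the exact permutation test over the 2000 assignments of water within the progenitors, p was 5e-04, the smallest it can give (0.013 adjusted over the 26 lists). Water was shuffled in each progenitor separately. The p therefore holds only if the progenitors share no animals, which the labels do not say. Limma, camera and fry also treated the arrays as independent, so their values over the 3 progenitors, the 114 calls included, carry the same limit.

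**Figure D3:**
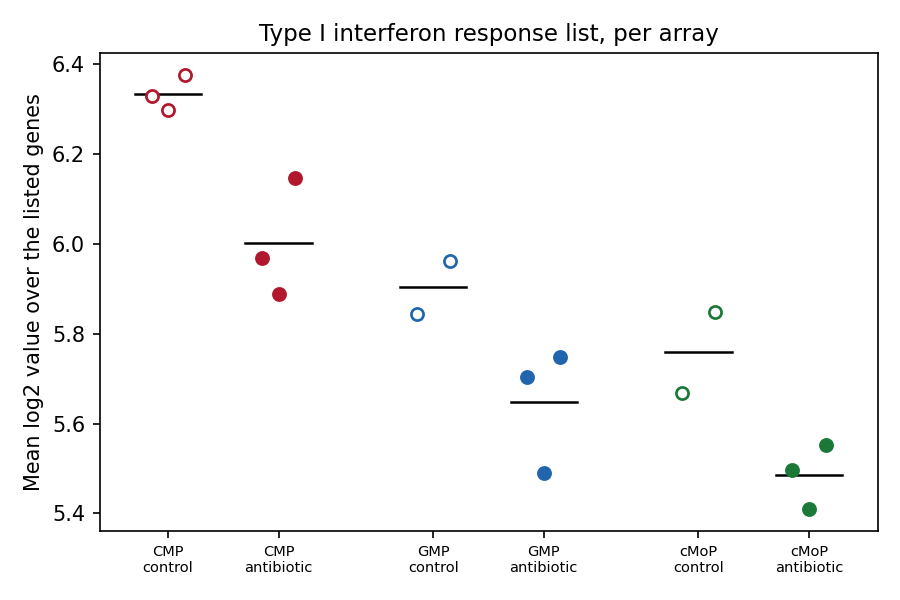
Mean log2 signal of the type I interferon list on each array, by progenitor and water, with a line at each group mean. In each progenitor the antibiotic arrays lie below the control arrays, at 6.00 against 6.33 in CMPs, 5.65 against 5.90 in GMPs and 5.49 against 5.76 in cMoPs.

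Genes of the interferon-gamma response were lower as a list over the progenitors, with 20 of 24 members negative and a mean of -0.18 (camera adjusted p = 4.92e-05; adjusted p = 0.257 with an estimated correlation). Gbp5, a guanylate-binding protein, fell by 0.75 ± 0.15 (adjusted p = 0.0817) and was the 1 member called over all genes, against 11 adjusted over the list alone. The immunoproteasome genes Psmb9 and Psmb8 differed by -0.27 ± 0.07 (adjusted p = 0.265) and -0.22 ± 0.08 (adjusted p = 0.381), and the peptide transporter Tap1 by -0.29 ± 0.1 (adjusted p = 0.34). The S phase list was lower, with 18 of 23 members negative and a mean of -0.07 (camera adjusted p = 0.028; adjusted p = 0.135 with an estimated correlation; fry adjusted p = 0.00277). Its mean was -0.12 in CMPs and -0.1 in GMPs, and 0 in cMoPs, where 13 of 23 members were positive. Its members of smallest p were the replicative helicase genes Mcm2 (-0.22 ± 0.08) and Mcm4 (-0.16), the licensing factor Cdt1 (-0.18) and Mcm5 (-0.15). Limma called 0 members over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05. The list of the unfolded protein and integrated stress response was lower, with 16 of 23 negative and a mean of -0.07 (camera adjusted p = 0.0342; adjusted p = 0.558 with an estimated correlation). The endoplasmic reticulum chaperones Hyou1 (-0.37 ± 0.08, adjusted p = 0.16) and Pdia6 (-0.31 ± 0.08, adjusted p = 0.183) were called over all genes, and 5 members were called adjusted over the list alone. Sdf2l1 and Calr differed by -0.31 (adjusted p = 0.277) and -0.21 (adjusted p = 0.331).

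Markers of 2 other lineages were higher as lists over the progenitors. Late granule and mature neutrophil genes had 16 of 24 members positive and a mean of 0.14 (camera adjusted p = 0.028; adjusted p = 0.647 with an estimated correlation). Chil3 was the 1 member called over all genes, and 2 higher and 1 lower were called adjusted over the list alone. In CMPs alone 13 of the 24 were negative (mean 0.03, median -0.05). Stfa1 differed by 0.71 ± 0.22 (adjusted p = 0.304), Ltf, lactoferrin, by -0.36 ± 0.12 (adjusted p = 0.323) and Cxcr2 by 0.31 ± 0.13 (adjusted p = 0.495). Erythroid genes had 14 of 20 members positive and a mean of 0.1 (camera adjusted p = 0.028; adjusted p = 0.257 with an estimated correlation), with Car1 called over all genes and 3 members adjusted over the list alone. In cMoPs alone 13 of the 20 were negative (mean -0.03). Hemgn, Rhag and Aqp1 differed by 0.4 ± 0.13, 0.33 ± 0.11 and 0.24 ± 0.13. In all, 6 of the 26 lists were called over the progenitors, of which the type I interferon list also passed with an estimated correlation. Fry called 2 lists. The number was 3 without GMP antibiotic 1, without CMP antibiotic 2, without cMoP control 1 or without GMP control 2. The exact permutation test called 3, with an adjusted p of 0.0477 for interferon-gamma and for S phase. It assumes that the progenitors share no animals.

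The other 20 lists were not called over the progenitors. Monocyte genes had a mean of -0.07 (camera adjusted p = 0.3), and 4 members were called lower over all genes. These were Mpeg1, the macrophage perforin (-0.47 ± 0.11), the chemokine receptor genes Ccr2 (-0.47 ± 0.11) and Cx3cr1 (-0.49 ± 0.12), and F13a1, a clotting factor subunit (-0.43 ± 0.1). F13a1 differed by -1.15 in CMPs, -0.12 in GMPs and -0.02 in cMoPs. Adjusted over the list alone, 4 monocyte genes were called higher and 12 lower. The means were -0.08 for cholesterol synthesis (adjusted p = 0.108), 0.08 for glucocorticoid response (0.142) and 0.06 for primary granules and early neutrophils (0.182). They were 0.03 for ribosomal proteins (0.254), -0.06 for stem and multipotent progenitors and 0.06 for megakaryocytes (0.336 each) and -0.02 for glycolysis (0.383). Adjusted p was 0.437 for B lineage (0.05), dendritic cells with MHC class II (0.03), G2 and M phase (-0.04), immediate early genes (-0.13) and Toll-like receptor and NF-kB signalling (0.03). It was 0.461 for cytokine and growth factor receptors (-0.05), 0.524 for T and NK cells (0.02) and 0.606 for oxidative phosphorylation (-0.02) and for eosinophils, basophils and mast cells (0). The highest values were 0.676 for stromal and endothelial cells (0.01), 0.842 for the circadian clock (0) and 0.994 for macrophages (mean 0.02, median -0.04, camera direction down). Members called one by one included the interleukin 1 receptor Il1r1 (0.47 ± 0.11, adjusted p = 0.183), the MHC class II gene H2-Ab1 (0.43 ± 0.1, adjusted p = 0.192) and the growth factor receptor Pdgfrb (0.59 ± 0.12, adjusted p = 0.114). They also included ficolin B, Fcnb (0.62 ± 0.13, adjusted p = 0.119), the stem cell regulator Hoxa9 (-0.56 ± 0.13, adjusted p = 0.154) and the mucin Muc13 (-0.45 ± 0.09, adjusted p = 0.0688). Fcnb differed by -0.41 in CMPs, 1.08 in GMPs and 1.17 in cMoPs.

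**Figure D4:**
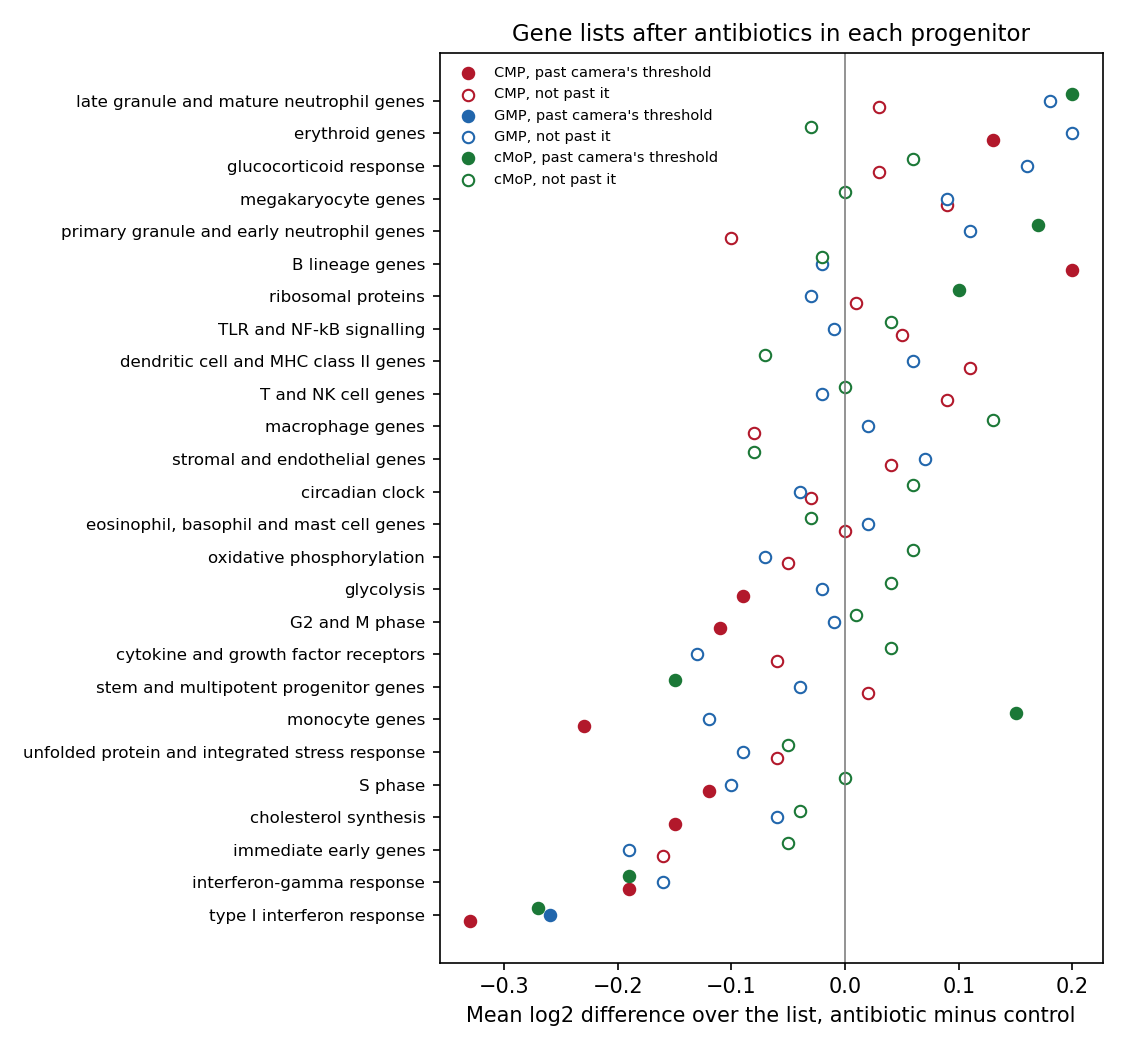
Mean log2 difference, antibiotic minus control, of each of the 26 gene lists in CMPs, GMPs and cMoPs, with filled symbols where camera called the list. The type I interferon list lies at -0.33, -0.26 and -0.27 and is filled in all 3 by the preset correlation, and monocyte genes lie at -0.23 in CMPs and at 0.15 in cMoPs.

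In CMPs, antibiotics raised Scin, an actin-severing protein (probe set 17280817), by 1.71 ± 0.18 (adjusted p = 0.00242), from 5.26 ± 0.24 (SD, n = 3) to 6.97 ± 0.28 (n = 3). The monocyte gene F13a1 fell from 7.72 ± 0.11 to 6.57 ± 0.4 (-1.15 ± 0.17, adjusted p = 0.0301). Tgfbi, an extracellular matrix protein, fell from 6.49 ± 0.39 to 5.41 ± 0.06 (-1.08 ± 0.17, adjusted p = 0.0685). Monocyte genes were lower as a list, with 27 of 36 members negative and a mean of -0.23 (camera adjusted p = 2.65e-05; adjusted p = 0.116 with an estimated correlation; fry adjusted p = 0.032). F13a1 and Tgfbi were the 2 called over all genes, and 12 were called lower adjusted over the list alone. Emb and Cx3cr1 differed by -0.55 ± 0.13 (adjusted p = 0.331) and -0.72 ± 0.19 (adjusted p = 0.357). The list mean was 6.29 ± 0.109 after antibiotics and 6.53 ± 0.06 in controls (SD, n = 3 each). Other genes that rose were Pkhd1l1, related to fibrocystin (0.9 ± 0.13, adjusted p = 0.0301), Fkbp7, a peptidyl-prolyl isomerase (1.03 ± 0.18, adjusted p = 0.118), and Asb17os (1.4 ± 0.24, adjusted p = 0.118). The microRNA gene Mir186 rose by 2.02 ± 0.36 (adjusted p = 0.134), the largest difference among the genes called in CMPs. Zfp811, a zinc finger gene, differed by -0.71 ± 0.13 (adjusted p = 0.133), from 2.9 to 2.19, which lies below the lower quartiles and is not shown to be above background. Cyyr1 fell by 1 ± 0.18 (adjusted p = 0.133), but as the mean of its probe sets it differed by -0.45 (adjusted p = 0.462).

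In CMPs the type I interferon list had 31 of 36 members negative, a mean of -0.33 and a median of -0.42 (camera adjusted p = 3.5e-10; adjusted p = 0.0717 with an estimated correlation; fry adjusted p = 0.0159). Limma called 0 of them over all genes, with 13 at an unadjusted p under 0.05, and 16 lower and 1 higher adjusted over the list alone. Oas3 differed by -0.86 ± 0.19 and Sp100 by -0.52 (adjusted p = 0.231 each). Interferon-gamma genes had a mean of -0.19 (camera adjusted p = 0.000908; adjusted p = 0.226 with an estimated correlation). The cell cycle lists were lower, S phase with 19 of 23 negative (mean -0.12, camera adjusted p = 0.00928; adjusted p = 0.0717 with an estimated correlation; fry adjusted p = 0.00372). G2 and M phase had 21 of 26 negative (mean -0.11, camera adjusted p = 0.0116; adjusted p = 0.255 with an estimated correlation). Their members of smallest p were Gins2 (-0.43), Uhrf1 (-0.3) and Mcm2 (-0.28), and the mitotic genes Ube2c (-0.5), Aurkb (-0.4) and Plk1 (-0.32). Cholesterol synthesis was lower, with Fdps at -0.47 (mean -0.15, camera adjusted p = 0.0224; adjusted p = 0.226 with an estimated correlation). Glycolysis was lower too, with Hk3 at -0.47 (mean -0.09, camera adjusted p = 0.041; adjusted p = 0.22 with an estimated correlation). Markers of 2 other lineages were higher. B lineage genes had 15 of 20 positive (mean 0.2, camera adjusted p = 0.0176, and adjusted p = 0.22 with an estimated correlation). Vpreb3 differed by 0.56. Erythroid genes had 14 of 20 positive (mean 0.13, camera adjusted p = 0.0231; adjusted p = 0.22 with an estimated correlation), and Rhag differed by 0.7 (adjusted p = 0.357). In all, 9 genes were called, 5 higher and 4 lower, 3 of them at a rate of 0.05, with 1606 at an unadjusted p under 0.05. The count was 2 without CMP antibiotic 1, 39 without CMP antibiotic 3, 14 without GMP antibiotic 3, 2 with all probe sets tested and 1 when only CMP arrays were fitted. The count of lists was 9, and 4 without CMP antibiotic 2.

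In GMPs, Car1 rose by 1.78 ± 0.2 (adjusted p = 0.00308; from 6.7 ± 0.16 SD, n = 2, to 8.48 ± 0.3, n = 3), against a level of 11.95 ± 0.08 (n = 3) in control CMPs. The 36 genes at least 8-fold higher in CMPs than in GMPs had a median difference of 0.109 in GMPs after antibiotics. The lectin genes Clec4b2 and Clec4a2 rose by 1.52 ± 0.26 (adjusted p = 0.0728) and 1.15 ± 0.18 (adjusted p = 0.0601), Chil3 by 1.19 ± 0.23 (adjusted p = 0.184) and Zbtb16 by 1.09 ± 0.22 (adjusted p = 0.197). Ly96, the MD-2 subunit of the endotoxin receptor, fell by 1.04 ± 0.2 (adjusted p = 0.184). Snord13 rose by 1.34 ± 0.17 (adjusted p = 0.00932), BC051142 by 1.1 ± 0.17 and Fmnl2, a formin, by 1.03 ± 0.17 (adjusted p = 0.0601 each), and Cep135, of the centriole, by 1.04 ± 0.19 (adjusted p = 0.137). Ppic fell by 1.23 ± 0.22 (adjusted p = 0.101), Smco4 by 1.19 ± 0.23 (adjusted p = 0.175) and Hormad2, a meiosis gene, by 1.1 ± 0.19 (adjusted p = 0.0728). The microRNA gene Mir23a fell by 2.15 ± 0.35 (adjusted p = 0.0601), the largest difference among the genes called in GMPs. Camera called 1 list, the type I interferon list, with 26 of 36 members negative and a mean of -0.26 (camera adjusted p = 0.00219; adjusted p = 0.467 with an estimated correlation; fry adjusted p = 0.256). Limma called 0 of its members over all genes, with 7 at an unadjusted p under 0.05, and 7 lower adjusted over the list alone. Fry called only the S phase list in GMPs, with 19 of 23 negative and a mean of -0.1 (fry adjusted p = 0.0161; camera adjusted p = 0.0651; adjusted p = 0.452 with an estimated correlation). Of the interferon members, Oas3 differed by -0.95 ± 0.21 (adjusted p = 0.285) and Xaf1 by -1.05 (adjusted p = 0.433). In all, 16 genes were called, 11 higher and 5 lower, 2 of them at a rate of 0.05, with 1662 at an unadjusted p under 0.05. The count was 2 without GMP antibiotic 1 or without GMP antibiotic 2, 42 without GMP antibiotic 3 and 0 when only GMP arrays were fitted. The interferon list missed its threshold without GMP antibiotic 2 (mean -0.177, adjusted p = 0.0577) and without GMP control 2 (-0.197, adjusted p = 0.0851). The lists called numbered 2 without GMP antibiotic 1, GMP antibiotic 2 or GMP control 1, 6 without GMP antibiotic 3 and 0 without GMP control 2.

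In cMoPs, the largest rise was in Clec4a2 (1.89 ± 0.18, adjusted p = 0.000484), from 5 ± 0.01 (SD, n = 2) to 6.9 ± 0.04 (n = 3). Lpl, lipoprotein lipase, rose by 1.44 ± 0.3 (adjusted p = 0.175) and Fads2, a fatty acid desaturase, by 1.25 ± 0.25 (adjusted p = 0.157). Cbr1, a carbonyl reductase, and Hal, histidine ammonia-lyase, rose by 1.25 ± 0.19 and 1.14 ± 0.17 (adjusted p = 0.0538 each), and the inhibitory receptor gene Lilrb4a by 1.39 ± 0.27 and Fcnb by 1.17 ± 0.23 (adjusted p = 0.14 each). Clec4b2 rose by 1.42 ± 0.26 and Snord65 by 1.58 ± 0.29 (adjusted p = 0.122 each), and Zbtb16 by 1.16 ± 0.22 (adjusted p = 0.129). Gdf3 fell by 1.33 ± 0.23 and Ppic by 1.2 ± 0.22 (adjusted p = 0.122 each). Other falls were of Zfp932 by 1.02 ± 0.21 (adjusted p = 0.181), Shisal2a by 0.81 ± 0.13 (adjusted p = 0.105) and Ccdc88b by 0.78 ± 0.16 (adjusted p = 0.172). Olfr695, an olfactory receptor gene, fell by 0.75 ± 0.14 (adjusted p = 0.122). In all, 29 genes were called, 20 higher and 9 lower, 1 of them at a rate of 0.05, with 1375 at an unadjusted p under 0.05. The count was 3 without cMoP control 1, 5, 6 and 9 without cMoP antibiotic 1, 2 and 3, 226 without cMoP control 2 and 4 without CMP antibiotic 2. It was 9 with all probe sets tested, 8 with unmoderated variances and 2 when only cMoP arrays were fitted.

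Camera called 7 lists in cMoPs, and with an estimated correlation the adjusted p of each of them was 0.661. By the preset test the type I interferon list was lower, with 28 of 36 members negative and a mean of -0.27 (camera adjusted p = 8.58e-05). So was the interferon-gamma list, with 21 of 24 negative and a mean of -0.19 (camera adjusted p = 0.0163). Limma called 0 type I members over all genes, with 9 at an unadjusted p under 0.05, and 10 lower adjusted over the list alone. Oasl2 differed by -0.85 (adjusted p = 0.554). Monocyte genes were higher, with 24 of 36 positive and a mean of 0.15 (camera adjusted p = 0.00636), at 8.01 ± 0.069 after antibiotics (SD, n = 3) and 7.86 ± 0.047 in controls (n = 2). Limma called 0 of these over all genes, with 8 at an unadjusted p under 0.05, and 4 higher and 1 lower adjusted over the list alone. Ifi30, a lysosomal thiol reductase, differed by 0.7 ± 0.18 (adjusted p = 0.448) and the fibronectin gene Fn1 by 0.99 (adjusted p = 0.587). Primary granule and early neutrophil genes (18 of 25 positive, mean 0.17) and ribosomal proteins (33 of 38 positive, mean 0.1) were higher (camera adjusted p = 0.00636 each). Fcnb was called in the first, and Rpl5 was at 0.69 (adjusted p = 0.617) in the second. Late granule and mature neutrophil genes were higher (16 of 24 positive, mean 0.2) and stem and multipotent progenitor genes lower (20 of 29 negative, mean -0.15; camera adjusted p = 0.0222 each). Chil3 was at 1.06 ± 0.23 (adjusted p = 0.248) and Hoxa9 at -0.92 (adjusted p = 0.382). Fry called 0 of the 26 lists. Without cMoP control 1, which stood apart on the fourth principal component, only the type I interferon (adjusted p = 1.82e-07) and interferon-gamma (0.00303) lists were called. With 1 control array left, the means of the other lists kept their signs and missed the threshold: 0.12 for monocyte genes (adjusted p = 0.158), 0.12 for primary granules (0.211), -0.11 for stem cells (0.213), 0.16 for late granules (0.283) and 0.05 for ribosomal proteins (0.56). There were also 2 lists without cMoP antibiotic 1 and 4 without cMoP control 2, where the type I interferon mean was -0.183 (adjusted p = 0.161).

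The effect of antibiotics differed between progenitors for 1 gene in the interaction test, Clec4a2 (probe set 17462764; adjusted p = 0.00233). It differed by -0.55 ± 0.16 in CMPs, where its level was 3.72 ± 0.18 against 4.27 ± 0.32 (SD, n = 3 each), and rose by 1.15 ± 0.18 in GMPs and by 1.89 ± 0.18 in cMoPs. Its adjusted p stayed between 0.000322 and 0.0205 when each of the 16 arrays was left out. The next genes by p did not pass the test: BC051142 (-0.44 in CMPs, 1.1 in GMPs and 0.29 in cMoPs) and Scin (1.71, 0.55 and -0.08) had an adjusted p of 0.218. Car1 (0.09, 1.78 and 0.7) had 0.223. Pkhd1l1 (0.9, -0.03 and -0.17, with GMPs and cMoPs at levels not shown to be above background), Ly96 (0.56, -1.04 and 0.2), Fcnb (-0.41, 1.08 and 1.17), Cyyr1 (-1, 0.27 and 0.42), Pilrb1 (-1.22, 1.81 and 0.24) and Zik1 (0.67, -0.25 and -0.63) had 0.269 each. In all, 1284 genes had an unadjusted interaction p under 0.05. Genes called with the same sign in both numbered 5 for GMPs and cMoPs, 0 for CMPs and GMPs and 0 for CMPs and cMoPs. Limma's unadjusted p was under 0.05 for 1606, 1662 and 1375 genes in CMPs, GMPs and cMoPs. The interaction count without 1 array was 24 without cMoP control 2, 8 without GMP control 1 and 5 without cMoP antibiotic 1 or CMP control 2. It was 3 without cMoP antibiotic 2, CMP antibiotic 2, GMP antibiotic 3 or cMoP control 1, and 2 without cMoP antibiotic 3, CMP antibiotic 3, CMP control 1 or GMP control 2.

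**Figure D5:**
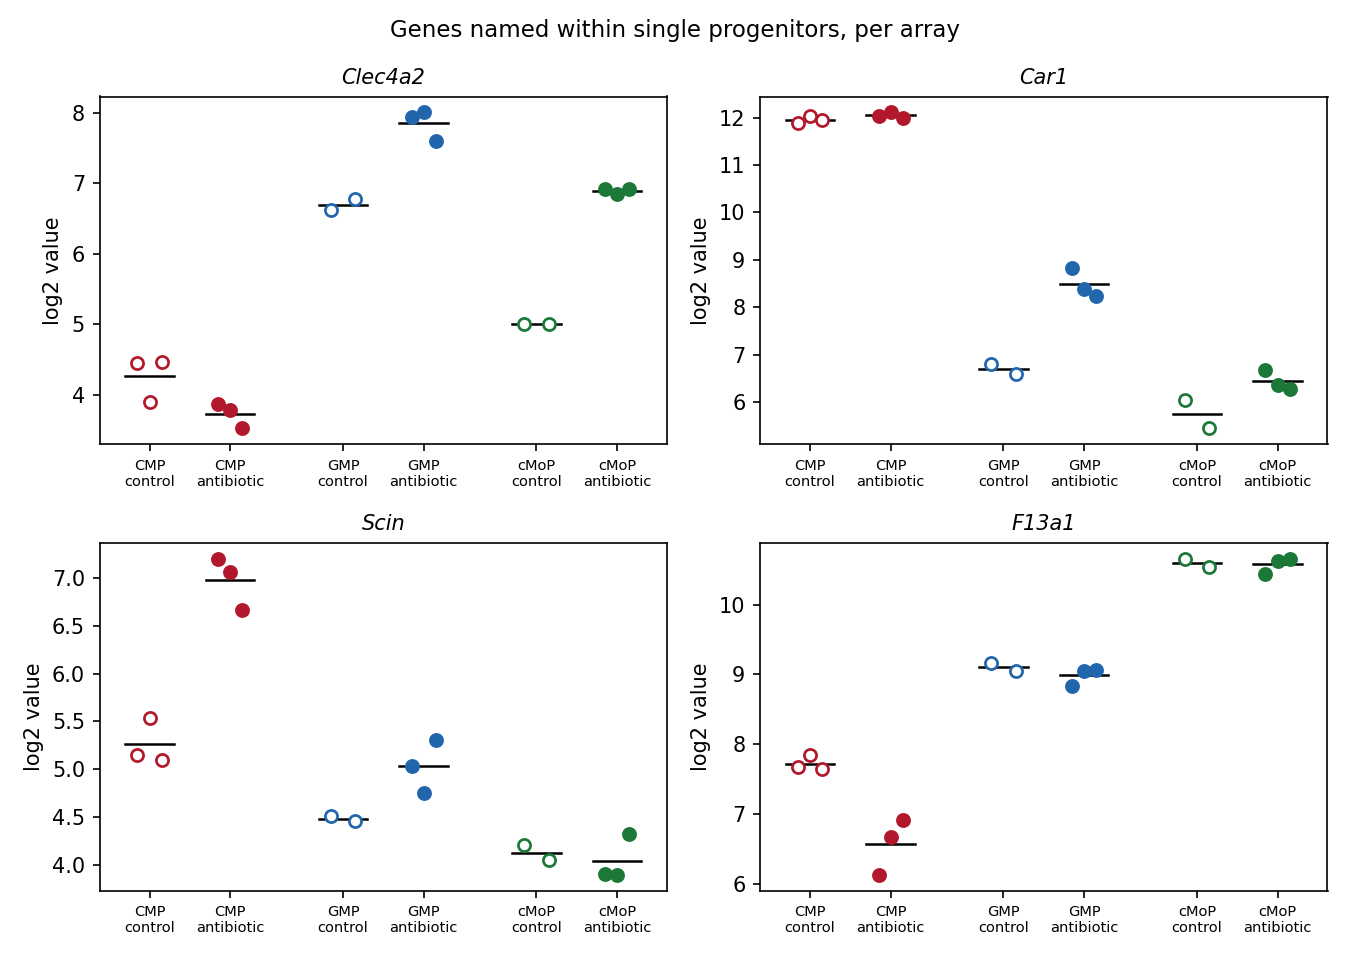
Log2 signal of Clec4a2, Car1, Scin and F13a1 on each array by progenitor and water, with a line at each group mean. Clec4a2 lies at 6.9 after antibiotics and 5 in controls in cMoPs, Car1 at 8.48 and 6.7 in GMPs, and in CMPs Scin lies at 6.97 and 5.26 and F13a1 at 6.57 and 7.72.

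Monocyte genes as a list moved differently in cMoPs than in CMPs, by a mean of 0.38 with 30 of 36 members positive. Over 78 tests the camera adjusted p was 1.12e-07, and 0.262 with an estimated correlation. The fry adjusted p of 0.0361 was adjusted only over the lists of this difference. It was not adjusted over the 78 tests, so it is not on the same scale. Monocyte genes also moved differently in cMoPs than in GMPs (mean 0.27, adjusted p = 0.00349, and adjusted p = 0.532 with an estimated correlation). The difference between cMoPs and CMPs was 0.27 for primary granule genes (adjusted p = 0.00612; adjusted p = 0.63 with an estimated correlation). The difference between cMoPs and GMPs was 0.12 for oxidative phosphorylation (adjusted p = 0.0341; adjusted p = 0.769 with an estimated correlation). Without cMoP control 1 the monocyte difference between cMoPs and CMPs passed (adjusted p = 3.44e-05). With 1 cMoP control array left, the other differences missed the threshold, at 0.24 for monocyte genes between cMoPs and GMPs (adjusted p = 0.0692), 0.23 for primary granule genes (0.106) and 0.07 for oxidative phosphorylation (0.403). Macrophage genes, not called with all arrays (mean 0.2, adjusted p = 0.0916; adjusted p = 0.602 with an estimated correlation), then passed between cMoPs and CMPs at the preset correlation (mean 0.31, adjusted p = 0.0464). Across all 22180 genes, which are not independent replicates, the antibiotic effects correlated at Pearson r = 0.148 (Spearman rho = 0.139) between CMPs and GMPs. They correlated at 0.109 (0.099) between GMPs and cMoPs and at 0.056 (0.037) between CMPs and cMoPs. Of 100 regroupings of water within the progenitors, the real one included, 1 was as high for CMPs and GMPs and 1 for GMPs and cMoPs, and 9 for CMPs and cMoPs. The highest other values were 0.093, 0.073 and 0.096. The regroupings assume that the progenitors share no animals, which the labels do not say. With each CMP or cMoP array left out in turn, the correlation between the effects in CMPs and cMoPs ranged from 0.017 to 0.08.

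Between GMPs and CMPs over both waters, granule genes were higher in GMPs and genes of the red cell, platelet and stem cell programmes were lower. Of 25 primary granule and early neutrophil genes, 24 were called higher (mean 1.87), with Cebpe, a transcription factor of granule formation (3.85 ± 0.17), Prss57 (2.99 ± 0.11), Fcnb (3.3 ± 0.15) and Mgst2 (2.66 ± 0.13). Of 20 erythroid genes, 18 were called lower (mean -2.99), with the Rh-complex genes Rhag (-4.83 ± 0.14) and Rhd (-3.73 ± 0.1), Car1 (-4.41 ± 0.13) and Ank1 (-2.84 ± 0.09). Of 29 stem and multipotent progenitor genes, 22 were lower (mean -1.07), with Gfi1b (-3.94 ± 0.13), Flt3 (-3.07 ± 0.12), Meis1 (-2.1 ± 0.12) and Angpt1 (-1.96 ± 0.12). Of 19 megakaryocyte genes, 14 were lower and 1 higher (mean -1.13), with Gata1 (-2.98 ± 0.12) and Gp5 (-2.85 ± 0.18). Camera's adjusted p was 4.77e-35, 4.76e-39, 3.04e-21 and 5.52e-13 for these lists in that order. With an estimated correlation the adjusted p was 0.00294, 7.81e-06, 0.000865 and 0.000865. Adjusted over the list alone, 24 were higher and 18, 22 and 15 lower. The largest rises included Olr1, the oxidized-LDL receptor (4.8 ± 0.14, adjusted p = 3.46e-12), the eosinophil granule genes Prg3 (4.34 ± 0.31), Epx (4.14 ± 0.23) and Prg2 (4.02 ± 0.34). Sgms2, Mgam, Far2, Rnase12 and Clec4b2 were higher by 3.76 to 4.17. The largest falls included Dntt, the terminal transferase of antigen-receptor rearrangement (-5.31 ± 0.18, adjusted p = 1e-11), and Ermap (-5.23). Other large falls were in the carboxylesterase gene Ces2g (-5.14), the water channel Aqp1 (-4.54), Cldn13 and Abcb4 (-4.39 each), Car2 (-4.28) and Tspan8 (-4.27).

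Other lists that differed between GMPs and CMPs included glycolysis, with 11 of 22 higher and 3 lower (mean 0.42, adjusted p = 1.9e-05; adjusted p = 0.0141 with an estimated correlation), led by Hk3 (2.11 ± 0.11), Vegfa (2.05 ± 0.12) and Pkm (1.13 ± 0.07). Dendritic and MHC class II genes had 8 of 23 lower (mean -0.39, adjusted p = 0.00187; adjusted p = 0.0313 with an estimated correlation), with H2-Aa at -1.32 ± 0.16. Monocyte genes had 18 of 36 higher and 4 lower (mean 0.45, adjusted p = 9.79e-05; adjusted p = 0.0667 with an estimated correlation), with Clec12a at 2.09 ± 0.12 and Slpi at 2.08 ± 0.13. Eosinophil, basophil and mast cell genes had 11 higher (mean 0.87, adjusted p = 2.24e-05; adjusted p = 0.0621 with an estimated correlation). The list of type I interferon genes had 9 of 36 lower (mean -0.39, adjusted p = 3.19e-06; adjusted p = 0.0621 with an estimated correlation), with Rtp4 at -1.96 ± 0.26 and Irf7 at -1.31 ± 0.2. In the unfolded protein and integrated stress response 14 of 23 were higher and 2 lower (mean 0.34, adjusted p = 3.19e-06; adjusted p = 0.0581 with an estimated correlation), with Sdf2l1 at 1.7 ± 0.11 and the amino acid synthesis gene Asns at -1.57 ± 0.11. In all, 3558 genes were called, 1745 higher and 1813 lower in GMPs, 858 of them at least 2-fold. The contrast of only the control groups called 1786 genes.

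Between cMoPs and GMPs, monocyte genes were higher in cMoPs and genes of eosinophils, basophils and mast cells were lower. Of 36 monocyte genes, 25 were called higher and 1 lower (26 and 2 adjusted over the list alone; mean 1.08, camera adjusted p = 7e-35; adjusted p = 0.00032 with an estimated correlation). They included the protease gene Ctss (2.37 ± 0.1, adjusted p = 1.83e-09), S100a4 (2.22 ± 0.13), the monocyte transcription factor Klf4 (2.65 ± 0.16) and Csf1r, the receptor CD115 (1.95 ± 0.13). Of 22 eosinophil, basophil and mast cell genes, 13 were lower (15 adjusted over the list alone; mean -1.54, adjusted p = 4.25e-25; adjusted p = 0.000795 with an estimated correlation). They included Cpa3 (-5.62 ± 0.15), Prg2 (-5.01 ± 0.36), Epx (-4.46 ± 0.24) and the IgE receptor subunit Ms4a2 (-2.68 ± 0.16). Of the 26 G2 and M phase genes, every one had a positive difference. Over all genes 6 were called (19 adjusted over the list alone; mean 0.31, adjusted p = 8.95e-13; adjusted p = 0.00673 with an estimated correlation), among them Kif23 (0.5), Bub1b (0.46), Aurkb (0.47) and Birc5 (0.55). Cytokine and growth factor receptors had 12 of 30 higher and 4 lower (mean 0.43, adjusted p = 6.11e-07; adjusted p = 0.00454 with an estimated correlation), with Il6st (2.33 ± 0.16), Il10ra (2.13 ± 0.18) and Ccr2 (1.55 ± 0.14). Stem and multipotent progenitor genes had 12 of 29 lower and 2 higher (mean -0.51, adjusted p = 2.75e-08; adjusted p = 0.0118 with an estimated correlation), with Angpt1 (-2.98 ± 0.12), Ikzf2 (-2.1), Myct1 (-2.14) and Gata2 (-1.95). Megakaryocyte genes had 8 of 19 lower (mean -0.71, adjusted p = 4.06e-13; adjusted p = 0.000795 with an estimated correlation) with Pf4 at -3.34 ± 0.25. Primary granule genes had 9 of 25 lower and 4 higher (mean -0.35, adjusted p = 2.75e-05; adjusted p = 0.213 with an estimated correlation) with Cebpe at -2.29 ± 0.18. Other large rises were in Pld4 (2.61), Tmem178 (2.58), the integrin gene Itga1 (2.56), Met, the HGF receptor (2.35), Ms4a4c (2.24) and AI839979 (2.2). Other large falls were in Rnase12 (-3.44), Ctla2a and Prg3 (-3.17 each), Ear6 (-3.01) and Prom1 (-2.74). The mean of Ctla2a in cMoPs after antibiotics was 2.84, below the lower quartiles and not shown to be above background. In all, 1202 genes were called, 577 higher and 625 lower, 324 of them at least 2-fold. The contrast of only the control groups called 385 genes.

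Between cMoPs and CMPs, 29 of 36 monocyte genes were higher in cMoPs (30 adjusted over the list alone; mean 1.52, camera adjusted p = 8.78e-28; adjusted p = 0.000226 with an estimated correlation). They included F13a1 (3.44 ± 0.12, adjusted p = 1.37e-11), Klf4 (3.35 ± 0.15), Slpi (2.8 ± 0.13) and Tgfbi (2.62 ± 0.13). Of 20 erythroid genes 18 were lower (mean -3.37), with Car1 (-5.9 ± 0.13), Mfsd2b (-4.9 ± 0.14), Rhag (-4.69 ± 0.14) and Rhd (-3.59 ± 0.1). Of 29 stem and multipotent progenitor genes 23 were lower and 1 higher (mean -1.58), with Gfi1b (-5.23 ± 0.13), Angpt1 (-4.93 ± 0.12) and Gata2 (-4.2 ± 0.16). Of 19 megakaryocyte genes 17 were lower (mean -1.83). Camera's adjusted p was 5.36e-38, 4.42e-26 and 3.18e-21 for these. With an estimated correlation the adjusted p was 8.89e-06, 0.000226 and 0.00015. Of 25 primary granule genes 23 were higher (mean 1.51, adjusted p = 1.51e-24; adjusted p = 0.00895 with an estimated correlation). Of 26 G2 and M phase genes 18 were higher (mean 0.39, adjusted p = 1.06e-08; adjusted p = 0.0192 with an estimated correlation). The type I interferon list had 18 of 36 lower (mean -0.55, adjusted p = 5.16e-08; adjusted p = 0.0298 with an estimated correlation), with Rtp4 at -3.59 ± 0.26 and the RNA sensor gene Ddx58 at -1.58 ± 0.14. Other large rises were in Nrg1, a neuregulin (4.31 ± 0.14, adjusted p = 3.62e-12), Gpr141 (4.22), Clec5a (4), Met (3.81), Ly6a2 (3.59), Papss2 (3.58), Aoah, which deacylates endotoxin (3.56), Itga1 (3.4) and Sgms2 (3.37). Other large falls were in Ces2g (-6.49 ± 0.14, adjusted p = 8.35e-14), the metallothionein Mt2 (-5.97), Car2 (-5.88), Ermap (-5.55), Ctla2a (-5.53), Dntt (-5.51), Cpa3 (-5.28) and Pf4 (-5.12). In all, 4195 genes were called, 2155 higher and 2040 lower, 1057 of them at least 2-fold. The contrast of only the control groups called 2271 genes.

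The genes of the sort gate served as a check of the labels. Csf1r, the gene of CD115, was higher in cMoPs than in GMPs (1.95 ± 0.13) and CMPs (2.53 ± 0.13). The CD16/32 genes Fcgr3 and Fcgr2b were higher in GMPs than in CMPs by 3.14 ± 0.15 and 2.08 ± 0.21. Ly6c2 and Ly6c1, of Ly6C, were higher in cMoPs than in CMPs by 2.41 ± 0.18 and 1.6 ± 0.19. Between cMoPs and GMPs they differed by 0.14 ± 0.19 and 0.56 ± 0.2, which did not pass the test. Kit was lower by -0.48 ± 0.09 in GMPs than in CMPs and by -1.1 ± 0.09 in cMoPs than in CMPs. Eng, the gene of CD105, was lower in GMPs and in cMoPs than in CMPs (-1.62 ± 0.18 and -1.21 ± 0.18). Itgam, the gene of CD11b, was higher in GMPs than in CMPs (1.11 ± 0.12) and lower in cMoPs than in GMPs (-0.97 ± 0.12). Itga2 and Thy1 were lower in cMoPs than in CMPs (-1.13 ± 0.21 and -1.11 ± 0.27). Between GMPs and CMPs and between cMoPs and GMPs, the lineage genes Cd4, Cd5, Cd8a, Itgax, Ly6g and Klrb1c differed by between -0.28 and 0.22 and did not pass the test. Ptprc differed by -0.04 ± 0.08 between GMPs and CMPs.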

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

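The tests of other cell types behind the interferon list, of cells like CMPs behind Car1 and of a single array behind Car1 were chosen only after the result was seen, and the rule that decides the test on the cMoP sort was made stricter after its first outcome. Clec4a2 drew attention because the interaction test found that its antibiotic effect differed between progenitors (adjusted p = 0.00233), at -0.55 in CMPs, 1.15 in GMPs and 1.89 in cMoPs. In the same kind of test on lists, monocyte genes moved differently in cMoPs than in CMPs (adjusted p = 1.12e-07) and in cMoPs than in GMPs (adjusted p = 0.00349). Primary granule genes moved differently in cMoPs than in CMPs (adjusted p = 0.00612), and genes of oxidative phosphorylation in cMoPs than in GMPs (adjusted p = 0.0341). With an estimated correlation the adjusted p of these 4 list differences was 0.262, 0.532, 0.63 and 0.769, so none of them passed.

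The type I interferon list was lower after antibiotics, with a mean difference of -0.29 over the 3 progenitors (adjusted p = 0.048 with an estimated correlation, which it did not pass within any 1 progenitor, at 0.0717, 0.467 and 0.661). The tables argue against a shift of all dim genes, since the lowest of 10000 random lists matched on signal had a mean of -0.088. They also argue against a single array as the source of the lower mean, which came no nearer to 0 than -0.258 without each array in turn. The test with an estimated correlation was not repeated without single arrays, so whether that call rests on 1 array is not shown. Fewer macrophages, dendritic or lymphoid cells in the sorts, which the lineage gate would remove, would lower their markers as well. Their 39 brighter markers had a mean of 0.063 with a standard error of 0.039. This mean pools several lists and the 3 progenitors, and progenitors may express markers this bright themselves, so it does not decide on a loss of few cells. Macrophage genes alone lay at 4.919 after antibiotics and 4.996 in controls in CMPs. The values were 4.925 and 4.904 in GMPs, and 4.512 and 4.386 in cMoPs. A response of the progenitors to antibiotics may underlie the list's fall, as a hypothesis found and tested on the same data. Such a loss of few cells stays open. So does any difference between sort or array days, or between animals shared by the progenitors, which the labels do not give.

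Monocyte genes were lower in CMPs and higher in cMoPs after antibiotics by the preset test (adjusted p = 0.116 and 0.661 with an estimated correlation). Without cMoP control 1 the difference between cMoPs and CMPs was 0.35 (adjusted p = 3.44e-05), which argues against that array as the whole cause, and within cMoPs the mean was 0.12 without it and 0.15 with it, although the call was lost with 1 control array left (adjusted p = 0.158). A CMP sort with fewer cells like cMoPs would lower genes that are high in cMoPs, and more so those with a larger fold. The 81 such genes off the list (at least 4-fold higher in cMoPs) had a median of -0.253 in CMPs. The 11 listed ones had -0.58, a gap beyond its standard error of 0.132. The listed and other genes were not matched on their fold, so the gap does not decide against such a sort. Of the 81, 64 were lower. For a cMoP sort with more cells late on the path from GMPs, the median was 0.152 over 13 genes off the list and 0.188 over the 5 listed ones, with a standard error of 0.259, too few genes to decide, so this and a change within cMoPs cannot be told apart.

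Car1, which is at 11.95 in control CMPs, rose by 1.78 in GMPs, and cells like CMPs at a share of 6.2 percent in the antibiotic GMP sorts could explain it. Such a share would raise the 36 genes at least 8-fold higher in CMPs by a median of 0.932, and their median was 0.109 with a standard error of 0.067; Ermap was at 0.29 where 1.84 was predicted, Ces2g at 0.28 where 1.77 was, Dntt at -0.1 where 1.76 was and Hemgn, among the nearest, at 0.71 where 1.03 was. Of the 36, 23 were positive, so a smaller share may still contribute. A single array is argued against by a gap of 1.44 between the lowest antibiotic array, at 8.25, and the highest control array. Erythroid genes as a list, Car1 included, lay at 5.32 ± 0.103 (SD, n = 3) in GMPs after antibiotics and 5.124 ± 0.086 (n = 2) in controls. Camera did not call the list there, but the lowest antibiotic array (5.247) lay above the highest control array (5.185). A rise of Car1 within GMPs may remain, as a hypothesis, beside a subset of erythroid cells in which the other genes are low, which was not tested.

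Other groupings of the same arrays tested whether chance could give the counts. For genes changed over the 3 progenitors, 1 of 100 regroupings of water within progenitors was as large, the real one at 114. The highest other was at 3. These counts exclude chance only if the progenitors share no animals, because the regroupings break up any animals they share. For the lists over the 3 progenitors chance cannot be excluded, with 5 of 100 as large. The real one was at 6 and the highest other at 10. In CMPs, 10 splits are too few for a share under 0.05: 9 genes were called in the real split and 11 in the highest other, and 9 lists in the real split and 10 in the highest other, with 2 splits as large in each case. For the differences between progenitors chance can be excluded in each pair, with 1 regrouping as large: 3558 genes against 2362 in the highest other for GMPs and CMPs, 1202 against 3 for cMoPs and GMPs (60 regroupings) and 4195 against 3050 for cMoPs and CMPs. The cause of the counts of 2362 and 3050 in other regroupings was not tested. A regrouping can keep most of the true labels and so part of the difference between progenitors.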

How the results depend on the processing

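The exact permutation test of the lists and the values of the type I interferon list under the alternatives are tests chosen only after the result was seen. The count of 114 genes over the 3 progenitors lay between 96 and 120 under quantile normalization, median centring, the mean of probe sets, unmoderated variances, array weights, the additive model and both blocks. The cause of each shift below was not tested, except that fewer genes or arrays were tested under a filter, a fit of only the groups compared or a left-out array. For a design with few arrays, signal over background limits what dim genes can show.

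With only genes brighter than the median gene, the count was 353 over the progenitors, 35 in CMPs, 27 in GMPs and 3 for the interaction, and with all probe sets it was 59, 2 in CMPs, 9 in cMoPs and 2 for the interaction. With trend and robust variances it was 350, 61 in CMPs, 27 in GMPs and 9 for the interaction, and unmoderated it was 15 in CMPs, 2 in GMPs, 8 in cMoPs and 2 for the interaction. Quantile normalization gave 21 in CMPs and 2 for the interaction, and median centring 2 for the interaction; under median centring 38.5% of the 13 calls in CMPs were higher, against 55.6% of 9, which is 5 genes each, so only the calls of lower genes grew. At a rate of 0.05 the counts were 23, 3, 2 and 1 over the progenitors and in CMPs, GMPs and cMoPs. Fits of only the groups compared gave 1 in CMPs, 0 in GMPs and 2 in cMoPs, where limma's unadjusted p for all arrays was under 0.05 for 1662 genes in GMPs. Between progenitors, a rate of 0.2 gave 6051, 2438 and 7063 genes, and the contrast of only the control groups 1786, 385 and 2271, for GMPs and CMPs, cMoPs and GMPs, and cMoPs and CMPs. Apart from the fixed block and the left-out arrays, the other alternatives left these counts within 1.5 times.

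The replicate number as a block gave 120 genes over the progenitors, 16 in CMPs, 8 in cMoPs and 2 for the interaction, and 2 lists over the progenitors, 2 in GMPs and 4 in cMoPs. As a random block within water it had a consensus correlation of 0.011. Deviations from the group means of arrays with the same number and water had a median correlation of 0.049, with 2 of 15 pairs above 0.1, against -0.032 for other numbers. Within a progenitor, between waters, they had -0.022 against 0.019. Of 16 arrays, 1 correlated best with its own number in every other group, those of the other water included. Arrays of different waters come from different mice, so these checks cannot show shared animals. The check within water was higher for the same number, so shared animals are not excluded, and the arrays were treated as unpaired. Of the 114 genes, 105 were shared with the calls under quantile normalization, 112 with trend and robust variances, 92 under the filter, 80 with the block, 56 unmoderated and 32 with all probe sets.

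Camera with an estimated correlation called 1 list over the progenitors and 0 in CMPs, GMPs and cMoPs; fry called 2, 3, 1 and 0, and the exact permutation test 3 over the progenitors. In CMPs the filter and quantile normalization gave 5 lists each. The type I interferon mean of -0.334 in CMPs had an adjusted p of 0.0717 with an estimated correlation. That of -0.256 in GMPs had 0.467 with an estimated correlation and 0.256 with fry, and that of -0.272 in cMoPs had 0.661 and 0.413.

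The correlation of effects was 0.23 between CMPs and GMPs and 0.191 between GMPs and cMoPs under the filter, and 0.111 between CMPs and GMPs with all probe sets. With each array of the groups compared left out in turn, the counts ranged from 41 to 269 over the progenitors, 2 to 39 in CMPs, 2 to 42 in GMPs, 3 to 226 in cMoPs and 1 to 24 for the interaction. Without cMoP control 1, which stood apart, they were 57 over the progenitors and 3 in cMoPs, and without cMoP control 2 they were 269 and 226. Between progenitors they ranged from 2816 to 3415, 833 to 1066 and 3367 to 4171 without 1 array of the pair compared. Without 1 array of the third progenitor, which enters only the estimate of the spread, the highest counts were 3511 for GMPs and CMPs and 1209 for cMoPs and GMPs, and the count in cMoPs was 4 without CMP antibiotic 2. The correlations ranged from 0.117 to 0.152 for CMPs and GMPs, 0.017 to 0.08 for CMPs and cMoPs and 0.068 to 0.126 for GMPs and cMoPs. Lists ranged from 3 to 6 over the progenitors, 4 to 12 in CMPs, 0 to 6 in GMPs and 2 to 7 in cMoPs. The interferon mean ranged from -0.317 to -0.258 over the progenitors, -0.407 to -0.277 in CMPs, -0.315 to -0.177 in GMPs and -0.362 to -0.183 in cMoPs. Of 448 values of named genes under the alternatives, 366 passed as before, 82 did not pass and 0 reversed. Unmoderated variances and trend and robust variances leave the differences themselves unchanged, so no value could reverse there. The filter and the alternatives on probe sets were not among these. The losses were uneven: of 56 values each, 32 did not pass without the array whose loss left the smallest difference and 31 did not pass unmoderated.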

Other observations

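Both tests reported here were fixed before the values they measure were seen, but only after the named genes had drawn attention to these groups; the estimated correlation was added to the second afterwards. Fabp4 rose over the progenitors and Lpl in cMoPs, which are 2 genes of lipid handling picked from different comparisons, with no list of such genes tested. A shared rise of targets of PPAR, a lipid-sensing nuclear receptor, could link them, as a hypothesis. The other 22 targets measured had a mean difference of -0.054 over the progenitors, and 9 of them were positive, which camera did not call. By the rule fixed beforehand, missing camera's threshold counted against a shared rise. That reading was afterwards changed to undecided, because the members moved both ways. The negative mean and the minority of positive members show no shared rise of these targets. A rise of only some of them is not excluded.

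Small nucleolar RNAs were among the largest changes, with Snord13 and Snord72 higher over the progenitors, Snord118 lower and Snord65 higher in cMoPs. If all of them had shifted together, for example with RNA yield, the other 69 small nucleolar RNA genes would likely have moved by a similar amount. Their median difference was 0.089, with 46 positive and 0 called one by one. The group passed camera's threshold with the preset correlation (camera p = 0.00207) and with an estimated correlation of 0.0213 (camera p = 0.0287). This median is far below the 0.94 of Snord13, so the others showed no shared shift of that size. The named genes were picked for large differences, which partly fixed in advance that the others moved less, so the median does not decide their cause.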
